A study of Staphylococcus aureus subsp. aureus NCTC 8325 with 12 samples.

How the data were processed

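Staphylococcus aureus NCTC 8325, a laboratory strain, was profiled with and without azithromycin, a macrolide antibiotic that binds in the exit tunnel of the large ribosomal subunit. Per the labels' protocols, treated cultures received 25 µg/ml azithromycin for 15 min, and all cultures received 100 µg/ml chloramphenicol, an inhibitor of peptide bond formation, for 2 min before harvest. Cells were ground while frozen, ribosome-protected fragments (RPF) were made with micrococcal nuclease and taken from the monosome fraction of a sucrose gradient, and total mRNA was broken by alkaline hydrolysis, per the labels' protocols. rRNA was subtracted before the libraries were built. The labels name 3 kinds of library, called mRNA, RPF1 and RPF2 here, each with and without azithromycin and each in 2 replicates, which gives 12 libraries in 6 groups. They do not say how RPF1 and RPF2 differ, so these were kept apart. They also do not say whether replicates came from separate cultures, so all p-values measure the spread between these samples, which may be technical.

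The deposited values are read densities in RPM at each nucleotide of each strand, scaled so that every library has the same sum over its whole density, rRNA and tRNA included. CASAVA 1.8.2, Bowtie 0.12.0, Bowtie2, Cufflinks and Cuffdiff are named per the submitters' processing notes, with no role for each. The genome build and the treatment of reads that map to several places are not given in the sources used here. In the values, each read was spread over up to 19 positions. The worth of 1 read was found from the smallest isolated stretches of density in each library, and 100% of such stretches were whole numbers of reads within 0.02. Reads per gene were recovered by dividing the summed density by this worth. The recovered totals ranged from 1237844 to 10675666 reads per library, and those over coding genes from 223693 to 2464684. These are reads without molecular identifiers, so they say only how precise the counting was.

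Gene positions and names came from a RefSeq table of assembly ASM1342v1, which holds 2767 coding genes, of which 219 have a symbol. Since the density does not name a build, the table was checked against it. In each of 4 equal parts of the table, mean footprint density around the annotated starts peaked between −5 and −3 nt. The table gives no products and no sequence was used here, so amino acid, codon and motif content at pause sites were not analysed here. A gene was given the strand that held at least 90% of its footprint density, where it had at least 20 RPF reads. Of all coding genes, 1963 had a strand, 783 had too few reads and 21 had reads on both strands. 3 coding genes overlap a tRNA gene in the table (SAOUHSC_02412, SAOUHSC_02294 and SAOUHSC_02411) and were left out, which left 1960 genes. SAOUHSC_02412 alone, of 117 nt, held between 7.01% and 46.6% of the density over coding genes. The choice to leave these out rests on the annotation but was made after a first full set of results had been seen, and the counts with them kept are given beside the others where they differ by more than 1.5 times.

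The design had been fixed for whole read counts before the data were examined. Because the deposited values are RPM and not counts, the test used in its place was the one the same design held for other units. For each gene, the density over its coding sequence was rescaled so that all coding genes of a library sum to the total of an RPM scale, called coding RPM here, and log2 of this value plus a pseudocount of 1 was fitted with limma 3.58.1 (limma-trend) in R 4.3.3 with a mean for each of the 6 groups. Genes needed 10 reads at the median library size in at least 2 libraries and 15 reads in all, which left 1906 genes tested. Calls had a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + pseudocount) scale, which understates the change of genes with few reads, and they compare shares of coding density, since no spike-in was used here. The contrasts were azithromycin against untreated in mRNA, in RPF1 and in RPF2, each footprint change relative to the mRNA change as an interaction term, the difference of the azithromycin effects of RPF2 and RPF1, and RPF2 against RPF1 without azithromycin.

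Of 27 gene lists fixed before the data were examined, 17 had members by symbol in the table and 12 had at least 4 tested members. These are ribosomal proteins, aminoacyl-tRNA ligases, translation factors with ribosome rescue and hibernation, chaperones and protein quality control, peptidoglycan synthesis and cell wall stress, pyrimidine synthesis, glycolysis and pyruvate dehydrogenase, the TCA cycle, SOS response and DNA repair, RNA polymerase and RNA decay, protein secretion, and cell division. Since 219 of the 2767 coding genes have a symbol, most lists hold few of their genes. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and with fry, which tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. Genes named in the text followed a rule fixed before the data were examined. It took the 10 largest called changes in each direction with a symbol and the 2 largest without, with the libraries of both groups apart and a mean of at least 20 reads, and the 4 largest changes in each list. Where it gave more genes than are named here, those whose call held in all settings were mostly chosen, after their values had been seen. For polarity it took the 5 largest shifts in each direction, and for pauses the 8 highest ratios in each kind of footprint library.

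Polarity places the density of a gene between −1, all at the 5′ end, and 1, all at the 3′ end. It was tested by limma for genes with at least 100 reads in each library of the kind tested. The 5′ ratio is the mean density in codons 2 to 50 over that in the 100 codons that end at codon 200, in genes of at least 250 codons. A pause score is the density at a codon over the mean of its gene, without the first 15 and last 6 codons. An azithromycin-dependent pause had a score of at least 10 in both treated libraries and at least 4 times the untreated one, with 0.5 reads added, in genes with at least 0.5 reads per codon. Codons closer than 7 apart were merged into 1 site. For groups of 2 against 2 libraries an exact two-sided test cannot go below a p of 0.33, and no other test was run on library medians and pause counts. Pauses and profiles were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.

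The fits were tested on simulated data with 200 genes changed 4-fold or 16-fold, up or down at random. With changed genes outside the 100 most abundant ones, 65% and 94% were recovered in mRNA, 59% and 91% in RPF1, and 51% and 95% in RPF2. Of footprint changes relative to mRNA, 47% and 79% were recovered for RPF1 and 32% and 70% for RPF2. For the difference of the azithromycin effects the recovery was 44% and 73%. In that draw 13, 16 and 19 of 1706 unchanged genes were called in mRNA, RPF1 and RPF2. When abundant genes could change, 279 of 1706, 55 of 1705 and 24 of 1706 were called. The simulated changes were few and balanced in direction, while most genes called in the real footprint data were lower. These rates therefore need not hold for the real data. The alternatives were median-of-ratios scaling, other filters and pseudocounts, trimmed genes, the 10 most abundant genes left out, fits of fewer groups, voom weights on the recovered reads, the replicate number as a block, and each library left out in turn. When a library was left out, its partner was assumed to vary like the other groups.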

Results

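Ribosome footprints and total mRNA of Staphylococcus aureus NCTC 8325 were sequenced to measure how 15 min of azithromycin changed mRNA abundance, the translated mRNAs and the ribosome density along transcripts. The data comprised 12 libraries in 6 groups of 2, namely total mRNA and 2 kinds of footprint library, RPF1 and RPF2, each with and without the drug. Reads over coding genes numbered 2464684 and 1233861 in the untreated mRNA libraries and 309932 and 1048736 in the treated ones. Untreated RPF1 had 471207 and 1268460 and treated RPF1 435409 and 1020822, while untreated RPF2 had 1135990 and 450227 and treated RPF2 223693 and 362779. The 10 most abundant genes held between 14.7% and 36.2% of the coding density of a library. tRNA held 62.8% ± 8.58 (SD, n = 2) of all density in untreated mRNA libraries and 81.9% ± 6.36 in treated ones, and it was also higher in both treated libraries of each footprint kind. Within each group the replicates differed by more than counting noise, with a chi-square per degree of freedom between 5.98 and 46.0 over genes, so no pair was treated as copies of 1 library. This does not show that they came from separate cultures.

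In total mRNA, azithromycin lowered the share of aminoacyl-tRNA ligase genes, whose products charge tRNAs with amino acids. Of 14 such genes 8 fell and 0 rose, with a list median log2 change of −1.48. alaS, the alanyl-tRNA ligase, went from 514 ± 123 to 94.8 ± 33.3 coding RPM (SD, n = 2), a log2 change of −2.45 ± 0.39 (SE; limma adjusted p = 0.00159). gatB, a subunit of an amidotransferase that completes tRNA charging, fell by 2.15, the glycolytic enolase gene eno fell by 2.29, the purine nucleoside phosphorylase gene deoD fell by 2.51, the protease subunit gene clpP fell by 1.79 and the phosphotransacetylase gene eutD fell by 1.85 (log2). Among the genes that rose was SAOUHSC_02262, a coding gene of 141 nt without a symbol in the table, from 37.2 ± 4.36 to 781 ± 93.7 coding RPM, a log2 change of 4.36 ± 0.46 (limma adjusted p = 8.12e-05). tsf, which encodes elongation factor Ts, rose by a log2 change of 1.46 ± 0.30 (limma adjusted p = 0.00804), but its adjusted p was 0.115 without the first untreated mRNA library, 0.0720 without the first treated one and 0.0650 without the second treated one. Of the 32 mRNA changes that the rule for named genes tracked, 24 and 16 lost their call without the first and the second treated mRNA library and 21 and 14 without the first and the second untreated one. The 7 that kept it in all settings and without each library are alaS, gatB, eno, deoD, clpP, eutD and SAOUHSC_02262.

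Across all 1906 genes tested, limma called 228 in mRNA, 38 higher and 190 lower with azithromycin. Of these, 29 of the higher and 182 of the lower genes were called the same way in RPF1, and 5 genes the opposite way. Independent lists would share 3.43 and 95.4, although these lists share 1 spread estimate per gene. Footprint reads carried over into the mRNA libraries, which are left open below, were not excluded as a part of the mRNA rises. The median of all genes was −0.41 under scaling to total coding density and −0.02 under median-of-ratios scaling, where 80 of 179 called genes were higher (44.7% in place of 16.7%). Relative to that median, the ligase list stood at −1.07 and the 49 ribosomal protein genes at 0.63. The ribosomal list had a median of 0.22, with 2 genes higher and 2 lower, but of −0.23 with the genes that overlap tRNA genes kept. By camera the ligases were lower (adjusted p = 4.00e-06) and the ribosomal proteins higher (adjusted p = 2.56e-06) than other genes. Both had an adjusted p = 0.0639 with an estimated correlation, and no camera call of any comparison held with one. By fry the adjusted p was 0.000971 for the ligases and 0.0394 for the ribosomal proteins. Adjusted over the list alone, 12 ligase genes were lower, and 0 ribosomal protein genes were higher and 1 lower. The count of 228 rested on the mRNA libraries, being 46 and 94 without the first and the second untreated one and 41 and 84 without the first and the second treated one, and it was 367 with the 3 genes that overlap tRNA genes kept. It was higher too with the mRNA groups fitted alone (813, where the same setting gave 1024 in RPF1 and 832 in RPF2), with voom weights (495) and with a pseudocount of 5 (350).

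None of the other 10 lists passed camera in mRNA. Glycolysis came closest, with 4 of 5 genes lower and an adjusted p of 0.0527. It passed without either untreated RPF2 library (0.0389 and 0.0296), without the first treated mRNA library (0.0116) and without the second untreated mRNA library (0.0305). It also passed with median-of-ratios scaling (0.0492), no filter (0.0467), a pseudocount of 0.25 (0.0456) and voom weights (0.0474). The same held with overlapping genes kept (0.0204) and with the replicate number as a block (0.0499). Peptidoglycan synthesis had 2 of 7 genes lower (0.130), chaperones and protein quality control 3 of 9 (0.176), RNA polymerase and RNA decay 1 of 9 (0.285), the TCA cycle 0 of 5 (0.285), protein secretion 1 of 5 (0.457) and cell division 1 of 4 (0.631). Translation factors had 1 of 12 genes higher and 2 lower (0.929), SOS response and DNA repair 0 of 9 called (0.929) and pyrimidine synthesis 1 of 6 lower (0.957). By fry, which tests a list against no change and not against other genes, 6 of the 10 were lower, namely chaperones (adjusted p = 0.00177), glycolysis (0.0135), the TCA cycle (0.0225), RNA polymerase and RNA decay (0.0270), peptidoglycan synthesis (0.0380) and translation factors (0.0400). Protein secretion and cell division had 0.0641, pyrimidine synthesis 0.339 and SOS response and DNA repair 0.497. For translation factors, SOS response and pyrimidine synthesis the camera direction was up while the median and the mean were below 0. Camera sets the test statistics of a list against those of other genes. The median of SOS response and DNA repair was itself −0.037 from the median of all genes.

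In RPF1, footprints on aminoacyl-tRNA ligase genes fell for 13 of 14 genes, with a median log2 change of −4.06, and 0 rose. aspS, the aspartyl-tRNA ligase gene, went from 721 ± 135 to 18.5 ± 9.55 coding RPM (SD, n = 2), a log2 change of −5.29 ± 0.47 (SE; limma adjusted p = 8.47e-07), and alaS, pheT and leuS changed by −5.19 ± 0.39, −5.12 ± 0.42 and −5.26 ± 0.54. Footprints fell as well on single genes of other functions. rpoB, the β subunit of RNA polymerase, went from 3565 ± 1714 to 112 ± 35.4 coding RPM, a log2 change of −4.92 ± 0.37 (limma adjusted p = 3.47e-07), and the amidotransferase gene gatA, the triose-phosphate isomerase gene tpiA, the enolase gene eno and the uridylate kinase gene pyrH changed by −4.97, −4.94, −4.66 and −4.08.

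Footprints rose on a smaller set of genes. infC, which encodes an initiation factor, went from 3059 ± 857 to 17810 ± 2830 coding RPM in RPF1, a log2 change of 2.56 ± 0.38 (SE, n = 2; limma adjusted p = 7.32e-05). The ribosomal protein genes rplN, rpmA and rpmH had log2 changes of 1.79 ± 0.28, 1.64 ± 0.25 and 1.45 ± 0.34, and mraW, an rRNA methyltransferase gene, 1.92 ± 0.29. The highest rise among genes without a symbol was at SAOUHSC_00637, from 389 ± 19.4 to 38787 ± 6390 coding RPM, a log2 change of 6.63 ± 0.28 (limma adjusted p = 3.99e-09). Its mRNA stood at 1826 ± 350 and 6075 ± 2231 coding RPM. Not all ribosomal protein genes followed, since rpsA and rplI changed by −3.53 and −3.46.

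Over all genes limma called 1129 in RPF1, 172 higher and 957 lower with azithromycin. The all-gene median was −1.45, or −1.41 with the 31 genes without a read in both treated libraries and the 2 without one in both untreated ones set at a floor of 3 reads per library. Under median-of-ratios scaling the median was −0.38, and 437 of 977 called genes were higher (44.7% in place of 15.2%), so gene groups are given relative to the median too. The ligases stood at −2.60 from it and the ribosomal proteins at 1.68. By camera the ligases were lower (adjusted p = 0.000157, or adjusted p = 0.129 with an estimated correlation) and by fry (adjusted p = 5.39e-06), with 13 lower adjusted over the list alone. Ribosomal proteins had 12 genes higher and 7 lower, or 10 and 6 adjusted over the list alone, and were higher than other genes by camera (adjusted p = 3.30e-06, or adjusted p = 0.0715 with an estimated correlation), while fry gave an adjusted p of 0.195. Their median was 0.23 and 1.40 under median-of-ratios scaling, but −0.10 when the first 90 and last 15 nt of each gene were left out.

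None of the other 10 lists passed camera in RPF1, where 957 of all 1906 genes were lower. Against no change, 10 of the 10 were lower by fry, with adjusted p up to 0.00707, beside an all-gene median of −1.45. The TCA cycle had 5 of 5 genes lower, among them sucC and fumC with log2 changes of −3.29 ± 0.34 and −2.23 ± 0.40 (camera adjusted p = 0.263). Peptidoglycan synthesis had 6 of 7 lower, among them murD at −3.50 ± 0.41 (0.0616). It passed without the first treated RPF1 library (0.0419) and without the second untreated one (0.0468), and with median-of-ratios scaling (0.0481). RNA polymerase and RNA decay had 7 of 9 lower and 1 higher (0.258), pyrimidine synthesis 4 of 6 lower (0.287), glycolysis 3 of 5 lower and 1 higher (0.549) and translation factors 7 of 12 lower and 2 higher (0.538), with infB at −3.82 ± 0.28 and the release factor gene prfC at −4.37 ± 0.40. Chaperones and protein quality control had 6 of 9 lower (0.434), with trigger factor, tig, at −1.99 ± 0.25. SOS response and DNA repair had 5 of 9 lower (0.549), protein secretion 1 of 5 (0.641), where median-of-ratios scaling turned the median from −0.92 to 0.25, and cell division 2 of 4 lower and 1 higher (0.861). The last list had an upward camera direction with a median of −1.70 in RPF1, and it holds secA, a secretion ATPase gene that entered it by a synonym.

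RPF2 gave changes in the same direction for most genes called in RPF1. Ligase footprints fell for 13 of 14 genes in RPF2, with a median of −3.13, and alaS went from 428 ± 63.1 to 18.6 ± 1.00 coding RPM (SD, n = 2), a log2 change of −4.45 ± 0.39 (SE; limma adjusted p = 1.35e-06). gatA changed by −4.81, the phosphoglycerate kinase gene pgk by −4.61, deoD by −4.56, rpoB by −4.05, and sucC, which encodes a succinyl-CoA synthetase subunit, by −4.10. The genes mraW, infC, rplN and greA, a transcript cleavage factor gene, rose by log2 changes of 2.49 ± 0.29, 1.91 ± 0.38, 1.73 ± 0.28 and 1.87 ± 0.31, and the glucose-6-phosphate isomerase gene pgi rose by 1.42 ± 0.23. SAOUHSC_01896, without a symbol, rose by 5.72 ± 0.37 (limma adjusted p = 2.54e-07). Of the genes called in RPF1 and RPF2, 152 were higher in both and 724 lower in both, where 23.0 and 413 would be shared by independent lists, and 1 went in opposite directions. Across genes, which are not independent replicates, the changes had a Pearson correlation of 0.876. These comparisons share no library, but they share 1 spread estimate per gene from the fit of all groups. The calls are thus not independent, and the numbers for independent lists are only a guide. The labels also do not say whether RPF1 and RPF2 came from the same cultures. RPF2 may therefore not be an independent repeat of RPF1.

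Limma called 1078 genes in RPF2, 255 higher and 823 lower. The all-gene median was −0.99, or −0.84 with the 78 genes without a read in both treated libraries and the 2 without one in both untreated ones at the floor. It was −0.36 under median-of-ratios scaling, where 433 of 1052 called genes were higher (41.2% in place of 23.7%). The ligases stood at −2.14 from the median and by camera were lower than other genes (adjusted p = 0.000390, or adjusted p = 0.270 with an estimated correlation) and by fry (adjusted p = 1.30e-05), with 13 lower adjusted over the list alone. Ribosomal proteins, with 10 higher and 8 lower, or 8 and 7 adjusted over the list alone, stood at 1.11 from it and were higher than other genes by camera (adjusted p = 0.0188, or adjusted p = 0.326 with an estimated correlation), while fry gave an adjusted p of 0.884. Their median was 0.12 but their mean −0.02, and the median was −0.33 with gene ends left out and −0.22 with the genes that overlap tRNA genes kept. That call ended without the first untreated RPF2 library (0.0755), without the first treated one (0.0580), with the ends of genes left out (0.555) and with the genes that overlap tRNA genes kept (0.105).

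The other lists in RPF2 had 6 of 7 peptidoglycan genes lower (camera adjusted p = 0.0546), 7 of 9 RNA polymerase and RNA decay genes lower and 1 higher (0.126), 3 of 5 TCA cycle genes lower (0.341), and 6 of 9 SOS and DNA repair genes lower (0.341). ddl, the D-alanine ligase gene of wall synthesis, had a log2 change of −3.07 ± 0.39, the transcription factor gene nusA −3.96 ± 0.37 and the mismatch repair gene mutL −2.80 ± 0.52. The peptidoglycan list passed without the first untreated RPF1 library (0.0492), without the second untreated RPF2 library (0.0423) and with median-of-ratios scaling (0.0383), which also gave 0.0475 for RNA polymerase and RNA decay. The peptidoglycan list passed as well with the RPF2 groups fitted alone (0.0463), with voom weights (0.0418) and without the 10 most abundant genes (0.0479). With the replicate number as a block it also passed (0.0457). Translation factors had 7 of 12 lower and 2 higher (0.383), chaperones 6 of 9 lower and 1 higher (0.496), pyrimidine synthesis 3 of 6 lower (0.496) and glycolysis 3 of 5 lower and 1 higher (0.577). Protein secretion had 1 of 5 lower (0.898), with a median of −0.52 that median-of-ratios scaling turned to 0.16, and cell division 2 of 4 lower and 1 higher (0.898), with an upward camera direction and a median of −1.22. By fry 8 of these 10 lists were lower in RPF2, with adjusted p up to 0.00222, and protein secretion had 0.0769 and cell division 0.1001.

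**Figure D1:**
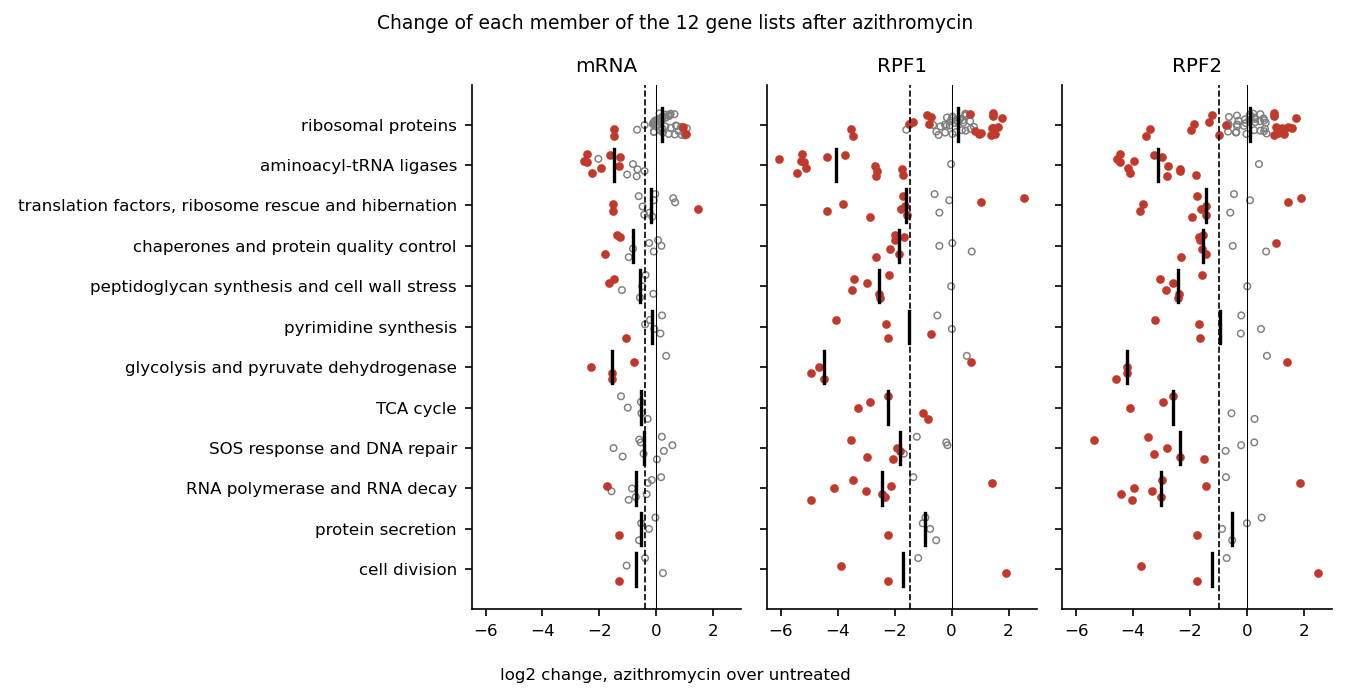
Log2 change with azithromycin over untreated of each tested member of the 12 gene lists in mRNA, RPF1 and RPF2 (points; filled red, limma adjusted p under 0.05; open grey, not), with the median of each list as a black bar and the median of all genes as a dashed line. Ligase medians lie at −1.48, −4.06 and −3.13 and ribosomal protein medians at 0.22, 0.23 and 0.12. With gene ends left out the latter lie at −0.10 in RPF1 and −0.33 in RPF2, and with the genes that overlap tRNA genes kept at −0.23 in mRNA and −0.22 in RPF2.

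Footprint change was set against mRNA change to ask which genes changed in ribosome occupancy per mRNA. Carry-over of footprint reads into the mRNA libraries, left open below, would act on the mRNA side of these values. The ligases fell further in RPF1 than in mRNA, with 11 of 14 genes lower, and valS, the valyl-tRNA ligase gene, fell by 3.09 relative to mRNA. tsf had the opposite changes in its mRNA and its footprints. Its mRNA went from 7982 ± 2542 to 21371 ± 1252 coding RPM and its RPF1 footprints from 5769 ± 1466 to 1639 ± 150 (SD, n = 2), a relative log2 change of −3.25 ± 0.43 (SE; limma adjusted p = 0.000640). rpoB had a relative change of −3.95 ± 0.53, pyrH −3.85 ± 0.43, the DNA polymerase gene polC −3.57 ± 0.69 and the termination factor gene rho −3.32 ± 0.50. SAOUHSC_00637 rose relative to mRNA by 4.93 ± 0.40 (limma adjusted p = 1.63e-05) and pgi by 1.48 ± 0.33 (limma adjusted p = 0.00730).

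In RPF1 relative to mRNA, limma called 399 genes, 62 higher and 337 lower, with an all-gene median of −0.99. Under median-of-ratios scaling the median was −0.30 and 139 of 301 called genes were higher (46.2% in place of 15.5%). The ligases stood at −1.49 from the median (camera adjusted p = 0.00200, or adjusted p = 0.329 with an estimated correlation), with 11 lower adjusted over the list alone. Ribosomal proteins stood at 1.01 from it with 1 gene higher and 4 lower, or 1 and 2 adjusted over the list alone, and camera gave them as higher than other genes (adjusted p = 0.0192, or adjusted p = 0.329 with an estimated correlation), with a median of 0.02 and a mean of −0.13. That call ended without the first untreated RPF1 library (0.601), without the second untreated mRNA library (0.151) and with gene ends left out (0.583). The count of 399 was 245 and 205 without the first and the second untreated mRNA library, 190 and 185 without the first and the second treated one, 241 without the first treated RPF1 library and 212 with the genes that overlap tRNA genes kept.

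Among the remaining lists in RPF1 relative to mRNA, peptidoglycan synthesis had 5 of 7 genes lower (camera adjusted p = 0.0762). It passed without the first untreated mRNA library or the second untreated RPF1 library. Pyrimidine synthesis had 2 of 6 lower (0.125), RNA polymerase and RNA decay 4 of 9 lower and 1 higher (0.217), and translation factors 6 of 12 lower and 1 higher (0.242). The TCA cycle had 2 of 5 lower (0.372), SOS and DNA repair 2 of 9 lower (0.574) and glycolysis 3 of 5 lower and 1 higher (0.651). Cell division had 1 of 4 higher (0.651), chaperones 1 of 9 lower (0.949) and protein secretion 0 of 5 called (0.949). The camera direction was up for cell division and protein secretion, with medians of −0.84 and −0.50. By fry the ligases (adjusted p = 0.000460) and 8 of these 10 lists were lower, with adjusted p up to 0.0479, and protein secretion had 0.207, cell division 0.367 and ribosomal proteins 0.367.

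In RPF2 relative to mRNA, tsf changed by −3.05 ± 0.43 (SE, n = 2; limma adjusted p = 0.00165), gatA by −3.30 ± 0.39, nusA by −3.11 ± 0.52, sucC by −3.10 ± 0.48 and the lysyl-tRNA ligase gene lysS by −2.13 ± 0.36. mraW, pgi and greA rose relative to their mRNA by 2.26 ± 0.40, 2.20 ± 0.33 and 2.17 ± 0.44. Limma called 366 genes, 113 higher and 253 lower, with an all-gene median of −0.57, and −0.33 under median-of-ratios scaling, where 149 of 354 were higher (42.1% in place of 30.9%). The ligases had 7 of 14 genes lower, stood at −1.20 from the median (camera adjusted p = 0.00903, or adjusted p = 0.480 with an estimated correlation), and adjusted over the list alone had 10 lower and 1 higher. The count of 366 was 198 and 174 without the first and the second untreated mRNA library and 152 and 182 without the first and the second treated one. It was 213 and 221 without the first and the second untreated RPF2 library.

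Ribosomal proteins in RPF2 relative to mRNA had 1 gene higher and 5 lower of 49 (camera adjusted p = 0.720), or 1 and 4 adjusted over the list alone, with a median of −0.18. Among the remaining lists, peptidoglycan synthesis had 3 of 7 lower (0.129) and RNA polymerase and RNA decay 5 of 9 lower and 1 higher (0.129). SOS and DNA repair had 2 of 9 lower (0.187) and translation factors 4 of 12 lower (0.187). Pyrimidine synthesis had 1 of 6 lower (0.387) and the TCA cycle 2 of 5 lower (0.387). Cell division had 1 of 4 higher (0.692), protein secretion 0 of 5 called (0.693), glycolysis 3 of 5 lower and 1 higher (0.693) and chaperones 1 of 9 lower and 1 higher (0.841). The camera direction was up for ribosomal proteins, cell division and chaperones, while their medians and means were below 0. By fry the ligases (adjusted p = 0.00203) and 6 of these 10 lists were lower, with adjusted p up to 0.0452, while ribosomal proteins, chaperones and glycolysis had 0.147, cell division 0.797 and protein secretion 0.920.

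No single gene separated the effect of azithromycin in RPF2 from that in RPF1. Limma called 0 of 1906 genes and voom 0, with 191 and 127 at an unadjusted p under 0.05. limma called 7 without the second untreated RPF1 library and 13 without the second treated RPF2 library. As a list, the ribosomal proteins were lower by camera in the difference of RPF2 minus RPF1 (median −0.11; adjusted p = 0.000179, or adjusted p = 0.154 with an estimated correlation). The ligases had a median difference of 0.61, close to the all-gene median of 0.41 (adjusted p = 0.656). Without azithromycin, limma called 0 genes between RPF2 and RPF1 and voom 0, with 21 and 16 at an unadjusted p under 0.05, and the ribosomal proteins had a median difference of 0.07 (camera adjusted p = 0.0554). By fry no list passed in the difference of effects or without azithromycin, with adjusted p of at least 0.323 and 0.944, and 1 list, chaperones in the difference of effects, had an unadjusted p under 0.05 (0.0401). Of the lists that did not pass in the difference of effects, translation factors and RNA polymerase and RNA decay had a downward camera direction with medians of 0.17 and 0.46, and the TCA cycle a median of −0.05 and a mean of 0.07.

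Along transcripts, footprints moved toward the 5′ end of more genes than toward the 3′ end. In RPF1, 97 of 219 genes shifted toward the 5′ end and 38 toward the 3′ end, and in RPF2 67 and 39 of 179. SAOUHSC_00525, which lies next to rpoB in the table, went from a polarity of 0.167 ± 0.0572 to −0.872 ± 0.00430 (SD, n = 2) in RPF1, with a limma adjusted p of 1.22e-05, and from 0.149 to −0.836 in RPF2. At codon 62 of the 1199 codons of this gene, the pause score was 707 and 663 in the treated RPF1 libraries. Its shift and that peak, described below, are therefore not separate findings. SAOUHSC_00908 and SAOUHSC_01035 shifted by −1.04 and −0.950 in RPF1, and the ribosomal protein gene rpsF by −0.865. Toward the 3′ end, gpsA, the glycerol-3-phosphate dehydrogenase gene, shifted by 1.11 ± 0.0604 (SE) in RPF1, asnC, the asparaginyl-tRNA ligase gene, by 0.780 in RPF1 and 0.807 in RPF2, and greA by 0.685 in RPF2. The polarity of gpsA in treated RPF1 was 0.919, close to the 3′ limit. Its footprint change in RPF2 reversed in sign when gene ends were left out.

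The median polarity over the 175 genes with at least 100 reads in every footprint library went from −0.0598 ± 0.0234 to −0.237 ± 0.0437 (SD, n = 2) in RPF1 and from −0.0855 ± 0.0173 to −0.220 ± 0.0245 in RPF2, and in mRNA it was 0.0333 ± 0.00292 and 0.0208 ± 0.00214. The 5′ ratio over 80 genes went from 1.14 and 1.26 to 1.72 ± 0.0886 in RPF1 and from 1.25 ± 0.0154 to 1.56 ± 0.0445 in RPF2. In mRNA it was 0.868 ± 0.0307 and 0.907 ± 0.0633. For 2 against 2 libraries the smallest exact two-sided p is 0.33, and no other test of these medians was run. When the polarity of the mRNA libraries was subtracted, limma called 82 genes in place of 135 in RPF1 and 66 in place of 106 in RPF2. The minimum of 100 reads set these counts too, as a minimum of 30 gave 296 and 224 and one of 300 gave 75 and 53.

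**Figure D2:**
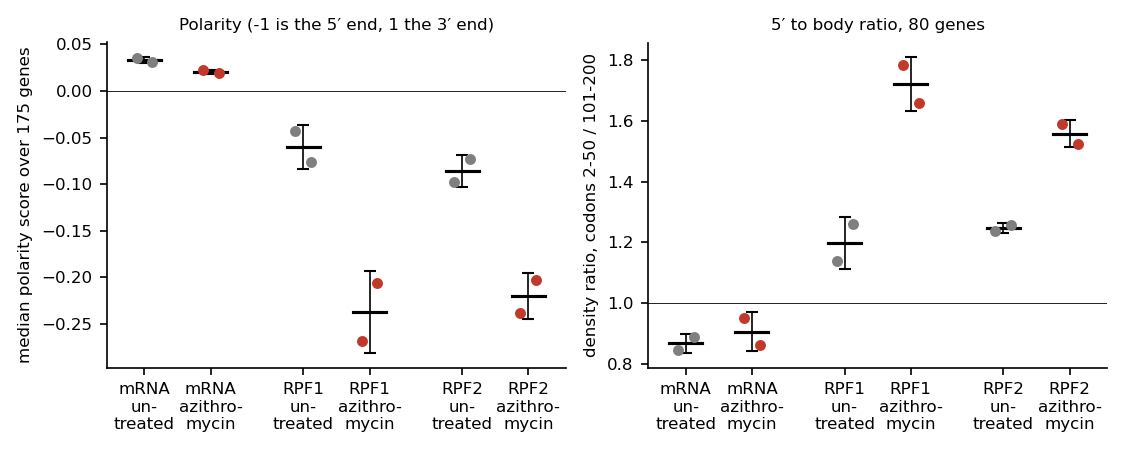
Median polarity over 175 genes (left, from −1 for all density at the 5′ end to 1 at the 3′ end) and the ratio of mean density in codons 2 to 50 over the 100 codons that end at codon 200 in 80 genes (right) for each library (points), with the mean as a bar and the SD as an error bar (n = 2). Treated RPF1 and RPF2 libraries lie below the untreated ones on the left, at means of −0.237 and −0.220, and above them on the right, at 1.72 and 1.56.

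Azithromycin also gave sharp peaks of ribosome density within genes. Each read was spread over several positions, so a peak can cover neighbouring codons, and the named codon only marks its place. The peak in SAOUHSC_02706 was named at codon 238 in RPF1 and at codon 239 in RPF2. Which codon the ribosomes stalled at was not determined. At codon 62 of SAOUHSC_00525 the pause score, the density over the mean of the gene, was 707 and 663 in the treated RPF1 libraries and 0.959 and 1.04 in the untreated ones. At codon 233 of dnaK, the gene of a chaperone, it was 98.3 and 137 in treated RPF1 against 0 and 0.189, and 100.5 and 86.0 in treated RPF2 against 0.119 and 0. At codon 135 of SAOUHSC_01149 it was 215 and 227 against 0 and 0.126 in RPF1, and at codon 238 of SAOUHSC_02706 115 and 120 against 0.0702 and 0.216. Codon 138 of SAOUHSC_00921 had 0 reads in both untreated RPF1 libraries, so its score was at least 91.6-fold higher with azithromycin against a floor of 3 reads per library, and in RPF2 at least 119-fold. In frr, which encodes the ribosome recycling factor, codon 111 had scores of 43.2 and 51.0 in treated RPF2 against 0.0290 and 0.0451.

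In RPF1, 317 of 34707 codons in 169 genes met the criteria, at 158 sites in 106 genes, and with treated and untreated exchanged 165 codons did. In RPF2, 221 of 23962 codons in 134 genes met them, at 114 sites in 84 genes, against 162 codons with the groups exchanged. Of 102 RPF1 sites in genes analysed in both, 92 lay at an RPF2 site, where random placement of the sites gave a mean of 8.84 and at most 18 (permutation p = 0.001 with 1000 placements, the smallest they can give). At a score of 5 the exchanged count was lower than the direct one in RPF1, 385 against 441, but higher in RPF2, 382 against 332. With a library left out, its group needed the score in 1 library and the other group in both, so these counts do not set the groups against each other on equal terms. Without the first and the second treated library, 550 and 387 codons met the criteria in RPF1 and 279 and 184 with the groups exchanged, and in RPF2 345 and 280 against 234 and 186. Without the first and the second untreated library there were 366 and 332 codons in RPF1 and 480 and 356 with the groups exchanged, and in RPF2 226 and 279 against 281 and 332. A minimum of 1 read per codon in place of 0.5 left out 7 of the named codons, since their genes have fewer reads. These were codon 380 of SAOUHSC_01150, codon 135 of SAOUHSC_01149 and codon 75 of SAOUHSC_00878 in RPF1, and codon 75 of SAOUHSC_00634, codon 302 of SAOUHSC_01040, codon 135 of SAOUHSC_01149 and codon 111 of frr in RPF2. In total mRNA, 129 of 62618 codons met the same criteria, at 54 sites in 49 genes, and 0 with the groups exchanged, with 388 codons without the first treated mRNA library.

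**Figure D3:**
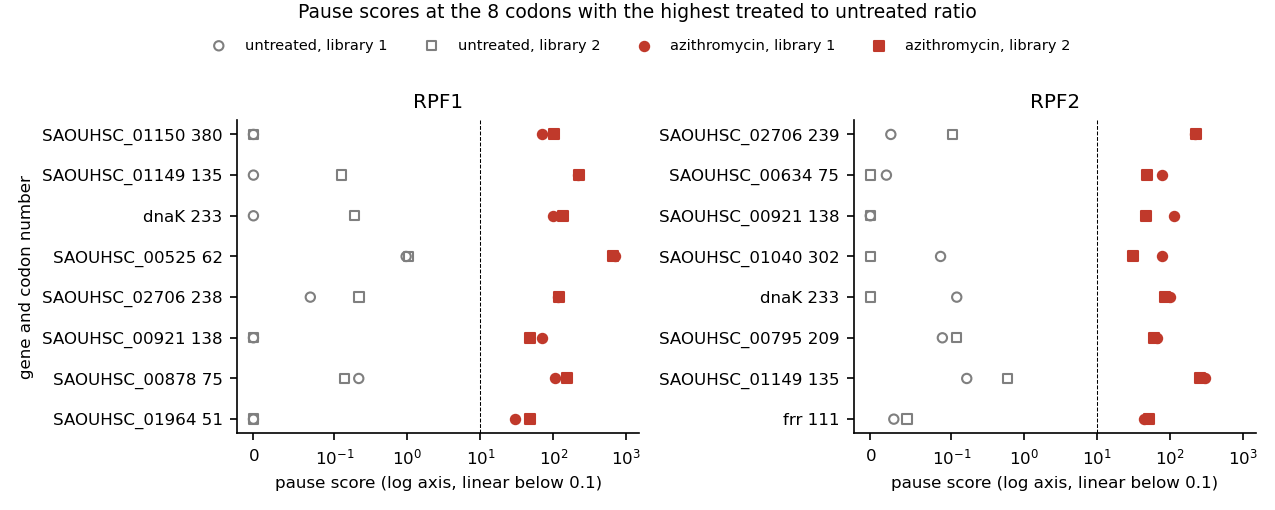
Pause scores (density at the codon over the mean of its gene; log axis, linear below 0.1) of each treated and untreated RPF1 and RPF2 library at the 8 codons named for each kind of footprint library, with the threshold of 10 as a dashed line. At codon 62 of SAOUHSC_00525 the treated RPF1 libraries lie at 707 and 663 and the untreated ones at 0.959 and 1.04.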

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

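The tests of unequal rRNA removal, of mRNA amount and of sequence bias, and the control matched on coding change, were chosen after the results they bear on had been seen.

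tRNA density, which no comparison of coding genes uses, took a larger share of both treated libraries than of both untreated ones in each kind of library. It held 81.9% ± 6.36 (SD, n = 2) of treated mRNA libraries against 62.8% ± 8.58 of untreated ones, 68.1% ± 4.94 against 45.5% and 62.5% in RPF1, and 82.8% ± 2.93 against 56.3% ± 5.28 in RPF2. Unequal removal of rRNA would leave the ratio of tRNA to coding density alike, but both treated libraries lay above both untreated ones in each kind. The ratio moved least in RPF1, from 1.19 and 2.26 untreated to 4.45 and 2.83 treated, with a mean 2.11 times as high. This argues against unequal rRNA removal as the whole cause. However, the ratio also differed widely between untreated replicates, in RPF1 and in mRNA, where it was 2.29 and 4.74. Of 59 tRNA genes, 26, 15 and 28 had both treated shares of density above both untreated ones in mRNA, RPF1 and RPF2, and 1, 6 and 6 had both below. Chance would give 9.83 in each direction if library labels were random. These genes are parts of the total share that was already seen to be higher, so the counts add no separate support. With no spike-in, more tRNA fragments and less coding RNA per cell stay open as explanations.

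Footprints of aminoacyl-tRNA ligase genes were lower than those of other genes by camera at its preset correlation, with adjusted p = 0.129 in RPF1 and adjusted p = 0.270 in RPF2 with an estimated correlation. Of 10000 random lists matched on coding length, 0% had a median RPF1 change as low as −4.06. Relative to mRNA, 21 of 10000 such lists were as low as the ligases in RPF1 and 113 in RPF2. These lists were not matched on abundance, and the pseudocount understates the falls of genes with few reads. Genes of like length thus rarely fell as far, but the part of length among genes of like abundance was not tested. A fall in proportion to their mRNA is not enough to give the lower footprints, since relative to mRNA the list stood at −1.49 from the median of all genes in RPF1. No lists matched on the mRNA change were drawn for footprints, so genes with a like mRNA loss were not compared. Part of the mRNA loss may come from transcription that stops in the leader, because in 7 ligase genes with a free leader of 200 nt the leader minus coding change had a median of 2.07 against 0.34 in other genes, above 100% of 10000 random lists. gltX, with a leader change of −1.14, was the exception among the 7. Its leader held 3.17 and 51.9 reads in the treated mRNA libraries and 143 and 56.1 in the untreated ones. The gltX value thus rests on few reads in the first treated library. In lists matched on the coding change, 22 of 10000 had a median as high as that of the ligases. Transcription that stops in the leader is a hypothesis on the mRNA part of the change alone. For the fall of footprints beyond it, coding length was the only explanation tested here.

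In genes analysed in both, most peaks of total mRNA density in treated libraries stood at the sites of footprint pauses, but of these pauses 30 of 139 RPF1 sites and 22 of 110 RPF2 sites were also mRNA sites. Of 34 mRNA sites in such genes, 30 lay at an RPF1 site, where random placement gave a mean of 2.59 and at most 8 (permutation p = 0.001 with 1000 placements, the smallest they can give), and 22 of 25 lay at an RPF2 site. A sequence bias shared by all mRNA libraries is argued against as the whole cause, since at the 158 RPF1 sites, which were chosen without the mRNA libraries, the median mRNA pause scores were 3.02 and 2.85 with azithromycin and 0.957 and 0.903 without, the lower treated one 2.97 times the higher untreated one. Footprint reads carried over into the mRNA libraries would give 1 ratio at all sites, and 53.7% of site values with at least 20 predicted reads were within 3 times of it, which is between the bounds set for and against. Carry-over and mRNA protected or broken at stalled ribosomes therefore cannot be told apart with these libraries.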

How the results depend on the processing

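The tests with pseudocounts of 0.25 and 5, voom weights, the genes that overlap tRNA genes kept and strands from mRNA, the 5′ ratio with at least 30 reads, and the pause counts and library medians without each library were chosen after seeing the data. Planned count tests and their scaling, and amino acid and motif tests, were not run, since the values are not counts and no sequence was used here. Of the counts and library values, 95 kept within 1.5 times or 1 SD in other settings and 23 moved, and the cause was not tested. Genes changed in mRNA numbered 228, and 813 with the mRNA groups alone, 350 with a pseudocount of 5, 495 with voom weights and 367 with overlapping genes kept, which gave 212 in place of 399 for RPF1 relative to mRNA. Shifted genes numbered 296 and 224 (RPF1 and RPF2) with at least 30 reads, 75 and 53 with at least 300, and 82 and 66 with the polarity of mRNA subtracted. The treated minus untreated 5′ ratio, 0.521 in RPF1 and 0.309 in RPF2, became 0.749 and 0.444 as a median over genes, 1.27 and 0.754 with summed reads, 0.687 and 0.461 for codons 16 to 50, and 0.254 in RPF2 with at least 30 reads. Pause codons numbered 203 and 134 at a score of 20, 156 and 140 with 1 read per codon, and in RPF2 332 at a score of 5.

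Without each library in turn, counts ranged from 41 to 329 in mRNA, from 881 to 1236 in RPF1, from 816 to 1134 in RPF2, from 185 to 560 for RPF1 and from 152 to 496 for RPF2 relative to mRNA, from 0 to 13 for the difference of effects, and 0 without azithromycin. The lowest of these came without a treated mRNA library in mRNA and relative to it (41 without the first, 185 without the second, 152 without the first), and 13 without the second treated RPF2 library. Pause codons ranged from 332 to 550 in RPF1 and from 226 to 345 in RPF2, the highest without the first treated library of each. Shifted genes ranged from 112 to 147 and from 89 to 113, the median polarity change from −0.208 to −0.146 and from −0.152 to −0.117, and the 5′ ratio change from 0.458 to 0.584 and from 0.277 to 0.340. With the ends of genes left out, rpsT and acpP in RPF1 reversed to −0.14 and −0.42, gpsA in RPF2 to −0.33 and acpP in RPF1 relative to mRNA to −0.29. With median-of-ratios scaling pyrC and sdhB in RPF1 reversed to 0.44 and 0.15. The cause was not tested. Of values of named genes, 2635 kept their call and 96 lost it in other settings, and 2462 kept and 280 lost it without 1 library. Named genes that kept it throughout were 7 of 32 in mRNA, 44 of 57 in RPF1, 49 of 58 in RPF2, and 25 of 42 and 20 of 40 relative to mRNA. Of list tests 704 kept their call, 13 gained and 3 lost one in other settings, and 706, 10 and 4 without 1 library. The replicate block gave 262, 1153, 1108, 447, 414, 0 and 0 genes in the order above and moved no count by over 1.5 times. Among list tests it gave calls for glycolysis in mRNA (0.0499) and peptidoglycan synthesis in RPF2 (0.0457). Replicate differences of same-numbered samples correlated across genes at 0.35, 0.27 and 0.21 between the 3 untreated groups, and between −0.03 and 0.09 in pairs with a treated group. Since not every pair was over 0.1, the numbers were not taken to pair the samples. Depth limits how many genes pause scores cover, since without the first treated library, the one with the fewest coding reads of its kind, 238 genes in place of 169 had enough reads in RPF1, 165 in place of 134 in RPF2 and 703 in place of 283 in mRNA.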

Other observations

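All tests in this part were chosen after the results had been seen, and none was planned. Footprint loss with azithromycin went with coding length. In RPF1 the median log2 change was −0.85 among the 477 shortest genes, of 30 to 166 codons, and −1.85 among the 477 longest, of at least 402 codons. In RPF2 the same medians were −0.52 and −1.38, and in mRNA −0.22 and −0.54. Across the 1906 genes, which are not independent replicates, the Spearman correlation with length was −0.207 in RPF1, −0.150 in RPF2 and −0.143 in mRNA. The fitted change per doubling of length was −0.43 in RPF1 and −0.33 in RPF2, and −0.26 and −0.15 with the mRNA change and the mean level of the gene in the fit. Ribosomal protein genes are short, with a median of 119 codons, but of 10000 random lists matched on length 0 had a median RPF1 change as high as 0.23, and 52 a median RPF2 change as high as 0.12. Relative to mRNA, 1 was as high as the 0.02 of the ribosomal list in RPF1 and 1469 as high as its −0.18 in RPF2. With gene ends left out the medians of the list were −0.10 in RPF1 and −0.33 in RPF2, and no matched lists were drawn for those values. The random lists were not matched on abundance.

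A few genes took much of the footprint density. SAOUHSC_01490, a coding gene of 273 nt without a symbol in the table that lies next to gpsA, held 2.39% and 3.05% of coding density in the untreated RPF2 libraries and 5.03% and 8.99% in the treated ones, while in mRNA it held 0.525% and 0.627% and then 0.791% and 0.594%. SAOUHSC_00529, listed with the synonym fusA, the elongation factor G gene, held 3.13% and 2.70% in untreated RPF1 and 0.373% and 0.431% in treated RPF1, and in mRNA 3.37% and 3.85% and then 2.87% and 3.72%. Density on the strand opposite to coding genes was 0.366% and 0.383% of coding density in untreated mRNA libraries and 0.857% and 0.750% in treated ones.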
